A study of Saccharomyces cerevisiae with 51 samples.

How the data were processed

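The series holds 51 samples of *Saccharomyces cerevisiae*: 24 RNA libraries and 24 ATAC libraries of the metabolic cycle, and 3 rapamycin RNA samples with 2 biological replicates each. Per the labels, RNA was extracted with a MasterPure kit, and the cycle libraries were prepared with the Illumina TruSeq mRNA kit, which 1 of the 3 rapamycin labels names too. Whether the libraries keep the strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The label of the rapamycin control names rapamycin in its treatment text although its title calls it the control. It was used as the control, after its title.

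The authors deposited FPKM values (fragments scaled by gene length and by a factor per library) for both sets of RNA libraries, in 1 table each, with 6840 and 6821 genes. The submitters' processing notes name Bowtie2, DESeq2 and Picard and the genome build sacCer3, without versions. How reads were assigned to genes is not given in the sources used here. Tests were made only within a table, since the tables were scaled separately. Each cycle column was matched to its sample by name, and the rapamycin columns by the replicate numbers that the labels give. The ATAC values were not analysed here: their 24 columns show the genotype but not the phase or the replicate, and no sample was assigned by column order. The planned comparisons of ATAC, and of RNA with ATAC, were therefore not run. Systematic gene names come from the tables, and standard names from the rapamycin table or, by locus tag, from RefSeq (assembly R64), which gave standard names to 5369 of 6840 and 5394 of 6821 genes. The position of ARP5 is from the same RefSeq table. Near-identical gene copies, such as the THI5 and PAU families and the ribosomal protein pairs, can share reads.

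FPKM are not counts. Low values fell on whole multiples of what 1 read is worth for 96.2% to 98.7% of the low values tested per library in the cycle table and 95.5% to 97.3% in the rapamycin table (tolerance 0.1 of a read). This gave depths of 5.03 to 9.68 and 9.45 to 13.6 M reads on annotated genes. The scaling factor recovered with them was not the read total. It was 5.06 M against 6.37 M reads on genes in wild-type RC start library A, and 7.19 M against 6.39 M in wild-type RB start library A. FPKM sums were not held equal, with 1.47 M in the first rapamycin control column and 0.92 M in the first 90 min column. All changes are relative to this scaling. Count tests were not run on these reads. The median gene had 37.6 to 41.7 FPKM. The 10 most abundant genes took 6.84% to 20.0% of the FPKM in the cycle libraries, most at RC start in wild type.

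Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, for genes with a mean of at least 1 FPKM over their table (6510 and 6333 genes). A fold change on this scale understates that of low genes. A call needed a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1 either way. The variance was moderated with an intensity trend. The per-phase contrasts, the F tests for cycling in each genotype and the F test of the 5 interaction terms came from a fit of 12 genotype-by-phase groups to all 24 libraries. For cycling and interaction the range over the phase means, or over the genotype differences, had to be at least 1. The comparison over the cycle used the 12 means of A and B with phase as a block, so that the phase is the unit. The rapamycin contrasts came from a fit of the 3 groups. Gene lists (26, of which 25 had members that passed the filter; the mitochondrially encoded genes had none) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Over-representation among cycling genes was tested with a Fisher's exact test (1-sided, adjusted over 25 lists). The main comparisons, the gene lists and the settings of the gene tests were written before the data were examined.

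Genes are named by a rule fixed at the same time: ARP5 and its complex first, then the 8 largest rises and 8 largest falls among called genes with a standard name that moved the same way in every replicate or phase (over the cycle and for each rapamycin time), the 12 widest ranges for cycling and interaction, the 3 largest rises and falls per phase, and up to 2 members per list and direction. SNZ1 at 45 min is named beside its value at 90 min.

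Replicates correlated with r of at least 0.988 across genes. The most genes differing at least 2-fold between A and B, at 10 FPKM or more, were 22 each at RC start and RB start in wild type, 19 of them higher in A at RC start.

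The steps were tested on simulated log2 values made from the real genes' means and spreads with 200 changed genes, 50 for each fold. With 2 libraries a group in 12 groups (6510 genes), 46% of changes of 2-fold, 96% of 3-fold and 98% of 4-fold were called. The interaction F test called 70%, 96% and 92%, and the cycling F test 76%, 96% and 96%. The comparison over the cycle, with the real spread between phases, called 16%, 56% and 70%. The rapamycin fit (6333 genes) called 50%, 98% and 100%. Of the unchanged genes at most 4 of 6310 (cycle) and 3 of 6133 (rapamycin) were called. Figures were drawn with matplotlib 3.10.9.

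Alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, no variance trend, leaving out each library or phase, a replicate block, only the 4 libraries of a phase, 24 libraries as separate samples, and other list tests. Chosen after the data were seen were the comparison of ranges between the genotypes with all its settings, the Fisher tests on cycling lists, the direct comparison of 90 with 45 min, the comparison without the phase block and the arp5∆ series moved by 1 to 5 positions. The settings other than the list tests for gene lists, rapamycin sets and phase alignment were also added after the data were seen.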

Results

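RNA was sequenced from budding yeast grown in continuous culture, a setting in which the cells pass together through repeated metabolic cycles. The samples carry the labels of 6 phases: start and mid of RC (reductive charging), mid and late OX (oxidative), and start and late RB (reductive building). Each phase was sampled in the wild-type strain CEN.PK and in the same strain with ARP5 replaced by a drug-resistance cassette (arp5∆). Arp5 is a subunit of INO80, a complex that moves nucleosomes, and the title of the series asks how this complex ties metabolism to cell division. Each of the 12 combinations of genotype and phase had 2 libraries, A and B, which are technical replicates made from RNA prepared separately from 1 culture. A further set of RNA libraries came from asynchronous cultures of the laboratory strain BY4741, with 2 biological replicates each for the control and for 45 and 90 min in 30 nM rapamycin, an inhibitor of the TORC1 kinase that promotes growth. The values show 5.03 to 9.68 M reads on annotated genes per library in the cycle set and 9.45 to 13.6 M in the rapamycin set. Because A and B share a culture, the adjusted p-values per phase, for cycling and for the interaction measure technical spread. Those of the comparison over the whole cycle measure the spread between phases. Each genotype rests on 1 culture.

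ARP5 (YNL059C, chromosome XIV, 512668 to 514935, a protein-coding gene) was read first, since it checks the labels. It had 50.7 ± 2.94 FPKM (SD, n = 12 libraries) in wild type, and was listed at 0 in 11 of the 12 arp5∆ libraries. Of the 15 measured members of the INO80 complex, ARP5 was the only member called between the genotypes over the cycle. The catalytic subunit gene INO80 had 26.0 ± 3.48 FPKM in wild type and 46.9 ± 3.61 in arp5∆ (SD over 6 phases), a log2 difference of 0.83 ± 0.13 (SE, adjusted p = 0.0327) that stayed under the 2-fold minimum. ARP4 had 110 ± 11.9 FPKM in wild type and 60.3 ± 3.04 in arp5∆ (log2 difference -0.85 ± 0.14, adjusted p = 0.0419), also under that minimum.

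The first question was which genes follow the cycle in wild type. Ribosome biogenesis genes peaked at OX mid: all 108 measured members cycled, 107 had their highest value there, and their median range over the phases was 4.67 (log2). DBP2, an RNA helicase gene of ribosome assembly, went from 4.02 FPKM at RC start to 1157 at OX mid (range 7.85), and NSR1, which encodes a nucleolar protein, had a range of 7.54. All 138 cytosolic ribosomal protein genes cycled too (median range 3.18), 137 of them with their peak at OX mid. All 19 genes of RNA polymerases I and III did the same (median range 3.21), and 39 of 44 amino acid biosynthesis genes cycled (2.32), with 36 of the 44 highest at OX mid. The 5 widest ranges among genes with a standard name were those of genes lowest at OX late. ADY2, which encodes an acetate transporter, had a range of 9.44, the widest of all, and ADH2, the ethanol-consuming alcohol dehydrogenase gene, came next. FDH1, a formate dehydrogenase gene, followed with 8.36, ACS1, the acetyl-CoA synthetase gene, with 8.27 and FOX2, which acts in peroxisomal fatty acid oxidation, with 8.10.

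Stress and storage genes had the opposite timing in wild type. All 26 genes of the stress and heat shock list cycled (median range 3.93), 19 with their peak at RC start, among them CTT1, the cytosolic catalase gene (7.26), and HSP12 (6.61). All 15 genes of trehalose and glycogen metabolism cycled (median range 4.78), led by TSL1 (6.92) and GLC3 (6.66). Of 68 mitochondrial ribosomal protein genes, 68 cycled and 62 peaked at RB late. The 8 core histone genes cycled as well, and 6 peaked at RB start. For G1/S and DNA replication 40 of 53 genes cycled and 36 of the 53 peaked at OX late, with MCD1 (2.98) and POL30 (2.71) leading. G2/M and mitotic exit genes peaked at RC start in 13 of 16 cases, and HOF1 (3.22) and SWI5 (2.94) had the largest ranges. In all, 4042 of 6510 tested genes cycled in wild type (limma F test, adjusted p under 0.05 and a range of at least 1), and 1651 of these peaked at OX mid. By Fisher's exact test, 15 of 25 lists held more cycling genes than the other tested genes did, with adjusted p = 2.77e-28 for ribosomal protein genes, while G2/M genes (adjusted p = 0.117) did not pass. This test treats genes as independent, although members of a list move together, so its p-values are too small. The cycling calls also rest on 1 culture.

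In arp5∆ the same large groups cycled over a smaller range. The median range of ribosome biogenesis genes was 2.40 (log2), and it was smaller than in wild type for all 108 genes. For cytosolic ribosomal protein genes it was 2.02 (smaller in 138 of 138), for trehalose and glycogen genes 2.33 (15 of 15), for stress genes 2.18 (25 of 26) and for mitochondrial ribosomal protein genes 1.18 (68 of 68). G2/M and mitotic exit genes kept the least: their median range was 1.84 in wild type and 0.47 in arp5∆, and 1 of 16 cycled in arp5∆. HOF1 had a range of 0.50 there and SWI5 one of 0.47. Core histone genes kept more, with 1.98 in wild type and 1.68 in arp5∆, and all 8 cycled in both. The genes with the widest range in arp5∆ were again ADY2 (7.18), ACS1 (6.56), ADH2 (6.35), FOX2 (6.26) and CTA1, the peroxisomal catalase gene (6.11).

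**Figure D1:**
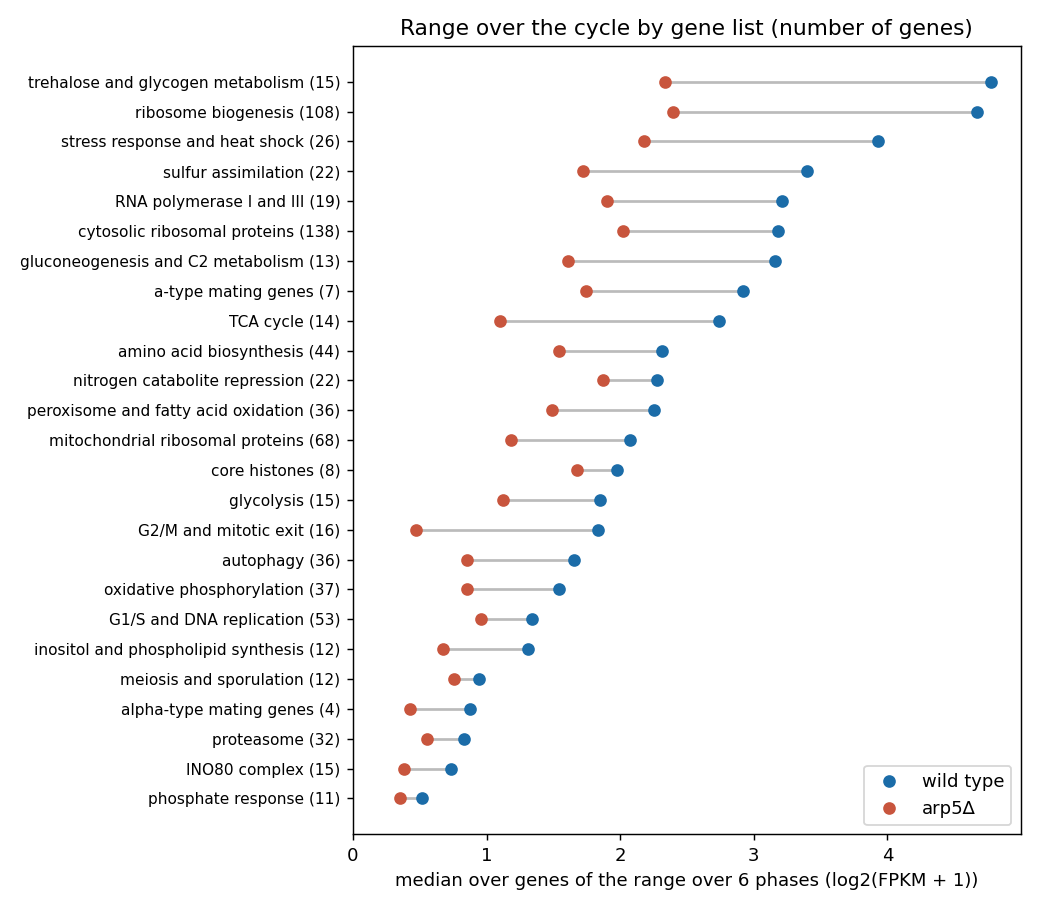
Range of expression over the 6 labelled phases for each gene list: the x axis is the median over the list's genes of the highest minus the lowest phase mean, in log2(FPKM + 1), with wild type in blue and arp5∆ in red, and the number of genes in brackets. In all 25 lists the median range is smaller in arp5∆, with the largest difference for trehalose and glycogen metabolism (4.78 against 2.33) and the smallest for phosphate response (0.52 against 0.35).

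Across all genes, 2104 cycled in arp5∆ by the same test. Of these 2029 also cycled in wild type, where independent lists would share 1306, while 2013 passed in wild type alone and 75 in arp5∆ alone. The median range over all 6510 genes was 1.34 in wild type and 0.74 in arp5∆, against 0.15 from simulated technical spread alone. It was 1.38 and 1.39 in the wild-type libraries A and B, and 0.79 in each of the arp5∆ libraries. The range was larger in wild type in 5802 genes (89.1%). It was larger by at least 1 in 1930 genes, and larger by at least 1 in arp5∆ in 24 (44 with a pseudocount of 0.1 and 42 without the filter on low values).

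Whether the course over the phases differed between the genotypes was tested itself. The genotype difference varied most over the phases for ADY2, by 15.04 (log2), and for ADH2, by 14.6. At OX late ADY2 had 4.84 FPKM in wild type and 3822 in arp5∆, whereas at RC start it had 3558 and 68.8. ACS1, FDH1, FOX2, SPG1 and CTA1 followed with 13.6, 13.0, 12.9, 12.5 and 12.5. FDH1 and ADH2 have close sequence relatives, so part of their reads may be shared. All genes of the lists for ribosome biogenesis, ribosomal proteins, RNA polymerases I and III, sulfur assimilation and core histones were among those called, while 11 of 16 G2/M genes and 5 of 15 INO80 complex genes were. In total 4817 of 6510 genes passed the limma interaction F test with a range of the difference of at least 1.

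Compared phase by phase under the labels, the groups changed sides from phase to phase. At RC start 106 of 108 ribosome biogenesis genes and 133 of 138 cytosolic ribosomal protein genes were higher in arp5∆ (median log2 differences 3.40 and 2.45), and 22 of 26 stress genes were lower (-2.50). NSR1 rose by 6.42 ± 0.08 (SE, n = 2), DBP2 by 6.19 and SAM1, a methionine adenosyltransferase gene, by 6.06, while RGI2 fell by 6.44 and SPG1 by 6.01. At OX mid 107 of 108 ribosome biogenesis genes and 137 of 138 ribosomal protein genes were lower in arp5∆ (medians -3.28 and -2.25), and 14 of 15 trehalose and glycogen genes were higher (4.56), with GSY1 up by 6.57 and GLC3 by 6.45. At OX late 28 of 53 G1/S and DNA replication genes were lower (median -1.03) and 12 of 13 genes of gluconeogenesis and C2 metabolism were higher (2.70). At RB start 50 of 68 mitochondrial ribosomal protein genes were lower (-1.28), and CTT1 rose by 6.93. At RB late 67 of these 68 were lower (-1.83), 97 of 108 ribosome biogenesis genes were higher (1.84), and PET117, a respiratory assembly gene, fell by 3.49 and SUC2, the invertase gene, by 3.32. At RC mid the a-type pheromone gene MFA1 rose by 4.03 and all 7 genes of the a-type mating list were higher (median 2.51), while SSA3, a heat shock protein gene, fell by 6.30.

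The number of genes called per phase ran from 1219 at RB start (653 higher and 566 lower in arp5∆) through 1366 at RC mid (646 and 720), 1445 at RB late (737 and 708), 1838 at OX late (959 and 879) and 2350 at RC start (1252 and 1098) to 2845 at OX mid (1413 and 1432). Counts for these lists adjusted over the list alone were the same as those over all genes. Each contrast rests on 2 technical replicates per group, with the spread shared over 24 libraries, and on the phase labels, which the transcript profiles of the cultures did not share, as described next.

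**Figure D2:**
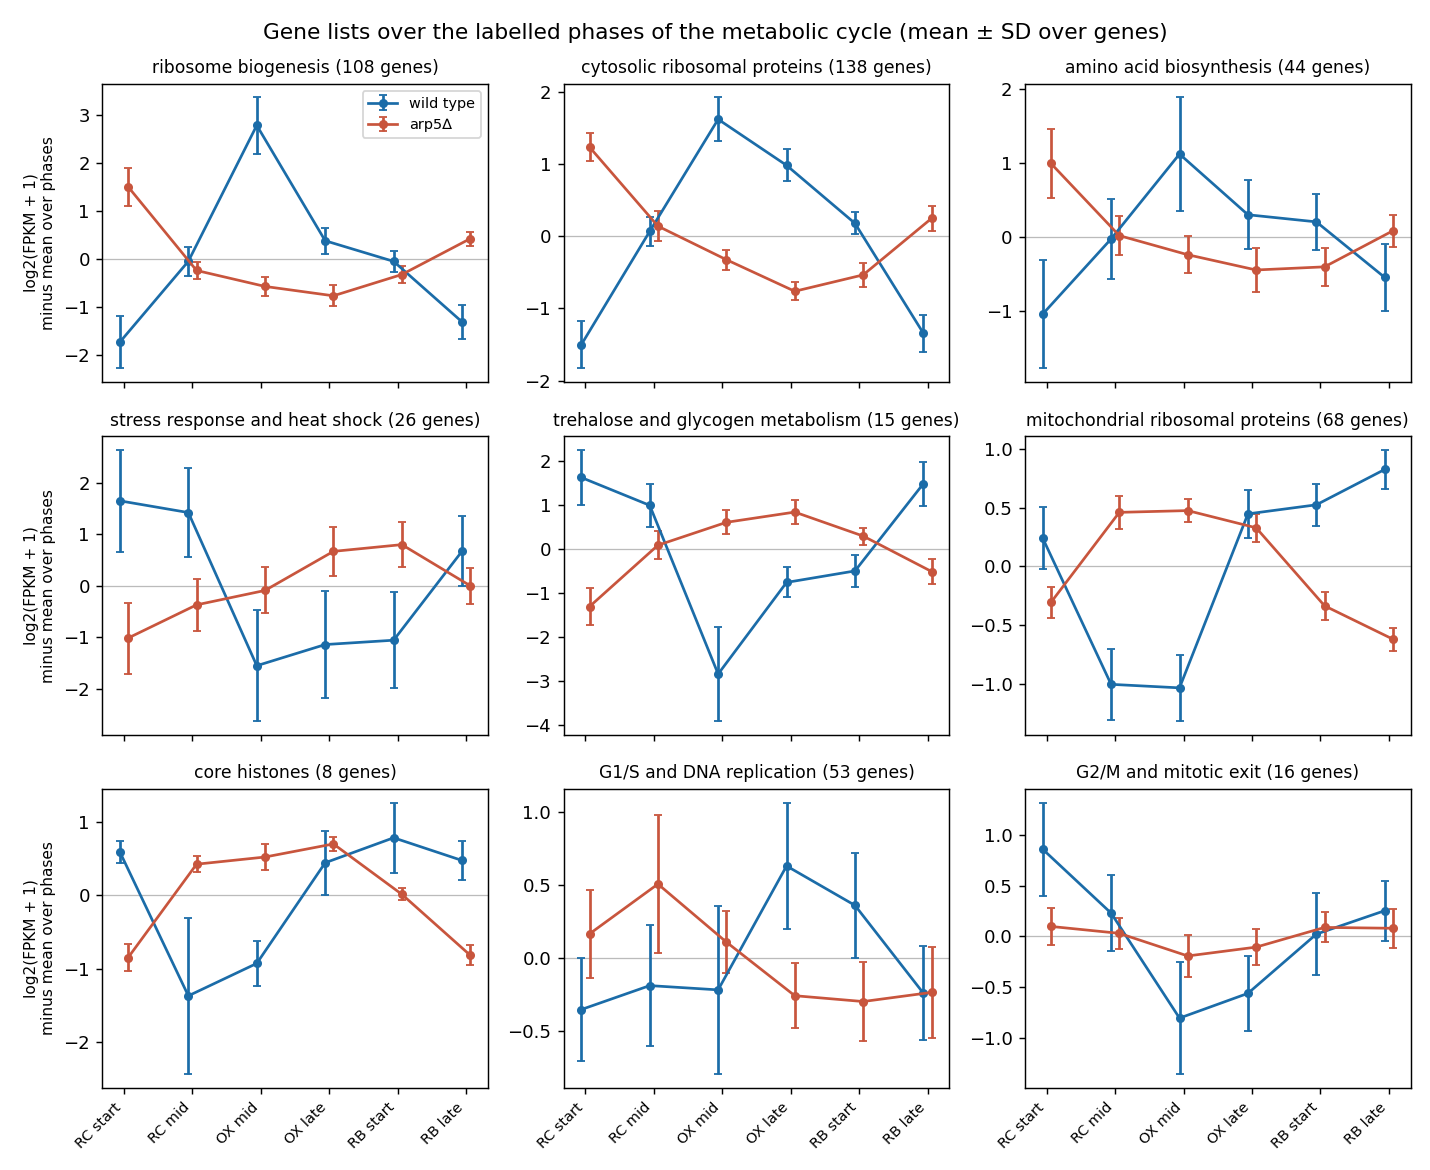
Mean expression of 9 gene lists over the labelled phases: the x axis is the phase, the y axis log2(FPKM + 1) minus each gene's mean over the phases of its genotype, points are means and bars SDs over the genes of the list, wild type in blue and arp5∆ in red. Ribosome biogenesis genes peak at OX mid in wild type and at RC start in arp5∆, and G2/M genes are nearly flat in arp5∆ (median range 0.47).

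The phases of the cultures did not match by label. Across the 4117 genes that cycled in either genotype, centred per gene over the 12 means, each arp5∆ phase correlated negatively with the wild-type phase of the same label, with r from -0.84 at RC start to -0.40 at RB late. The arp5∆ libraries labelled RC start resembled wild-type OX mid most (r = 0.73), those labelled OX late resembled wild-type RC start (0.65), and those labelled OX mid wild-type RB late (0.47). The best match lay 2 steps ahead for RC start and RB start and 3 steps ahead for the other phases. Centred within each genotype, RC mid matched OX late best, 2 steps ahead (r = 0.72, against 0.35 for its best match above), and r rose to 0.73 for OX mid and from 0.11 to 0.52 for RB late, with the other matches in place. Genes are not independent replicates, so this is a description. Taken singly, with the centring within genotypes, 12 of 12 arp5∆ libraries matched best a wild-type phase of another label, and A and B of each phase the same phase. By list, ribosome biogenesis genes peaked in arp5∆ in the libraries labelled RC start (107 of 108 genes), as did ribosomal protein genes (138 of 138) and 41 of 44 amino acid genes. Peroxisomal and fatty acid oxidation genes peaked in those labelled OX late (30 of 36), and so did 7 of 8 histone genes. By the mean profiles of the 25 lists, 16 matched best 2 steps ahead and 4 at 3 steps. G2/M and glycolysis matched best at the same label (r = 0.90 and 0.83), with mean profiles that ranged by only 0.29 each in arp5∆. The directions at single phases above therefore hold for the libraries as labelled.

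**Figure D3:**
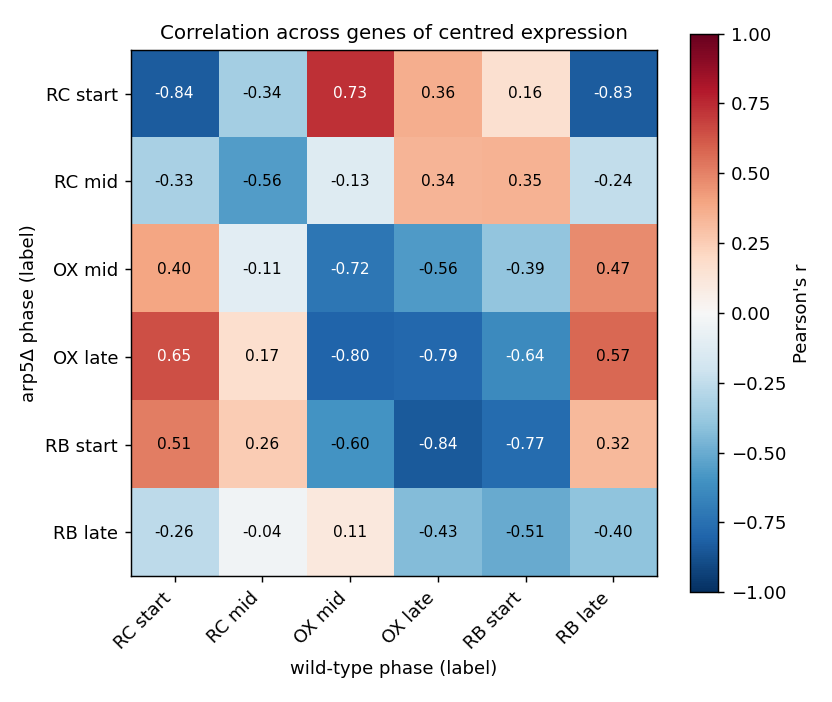
Pearson's r across 4117 genes between each arp5∆ phase (y axis, by label) and each wild-type phase (x axis, by label), on log2(FPKM + 1) centred per gene over the 12 genotype-by-phase means. The diagonal, where the labels are the same, runs from -0.84 to -0.40, and the highest value is 0.73 between arp5∆ RC start and wild-type OX mid.

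The genotypes were also compared over the whole cycle, with phase as a block. DAN1, a cell wall mannoprotein gene, had 1.84 ± 0.52 FPKM in wild type and 26.2 ± 8.10 in arp5∆ (SD over 6 phases, log2 difference 3.24 ± 0.27, adjusted p = 0.00648). DIP5, which encodes an amino acid permease, had 37.6 ± 29.7 and 348 ± 187 FPKM (3.23 ± 0.37), and THI5, a thiamine synthesis gene with near-identical copies, 43.9 ± 17.1 and 317 ± 71.2 (2.90 ± 0.24). Its copy THI12 was higher by 2.33, the meiotic genes GMC2, MAM1, SPR3 and SPO11 by 2.45, 2.43, 2.26 and 1.85, and SNR40 by 2.30. SNR40 is a small nucleolar RNA, and these libraries were made with an mRNA kit. RNAs without a poly(A) tail could differ widely between A and B of a culture, such as SCR1 with 577 and 10.9 FPKM at RC start in wild type. The value for SNR40 is therefore less certain. After ARP5, the largest falls were those of DSS4, a guanine nucleotide exchange factor gene, from 55.6 ± 14.7 to 10.9 ± 2.71 FPKM (log2 difference -2.24 ± 0.18, adjusted p = 0.00648), and of CPR2, a cyclophilin gene, by 2.15. KNH1, NEJ1, WIP1, LCL2 and ALG3 fell by 1.81, 1.75, 1.65, 1.65 and 1.57. Each of the genes named here moved the same way in 6 of 6 phases.

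Most lists had no member called over the cycle. Of the meiosis and sporulation list 2 of 12 genes rose, SPR3 and SPO11, and of the phosphate response list 2 of 11 fell, PHO89 (by 1.35) and PHO11 (by 1.10). No ribosome biogenesis gene of 108 passed (median log2 difference 0.07). Their median difference swung from 3.40 at RC start to -3.28 at OX mid under the labels. That spread enters the test, so the lack of calls does not show that they are unchanged. None of the 15 glycolysis genes passed either (median -0.57), where PGI1 had a difference of -0.82 and GPM1 one of -0.78. Among 13 genes of gluconeogenesis and C2 metabolism none passed over all genes and 2 were higher when adjusted over the list alone (median 1.48), with FBP1 at 2.42 ± 0.49. Likewise 2 of 16 G2/M genes (median 0.44; HOF1 at 1.30, SWI5 at 1.16) and 1 of 22 nitrogen genes were higher when adjusted over the list alone. For mitochondrial ribosomal proteins the median was -0.35 and for cytosolic ones -0.32, which became 0.01 under quantile normalization. Camera with a preset correlation called 10 of 25 lists, 4 up and 6 down, and none of them passed with an estimated correlation (lowest adjusted p = 0.441 with an estimated correlation, 2 lists with an unadjusted p under 0.05). Under quantile normalization the preset correlation called 10 lists too, but 8 up and 2 down. G2/M, gluconeogenesis and C2 metabolism and meiosis stayed up, and G1/S and phosphate response down. The other lists called before no longer passed, and those that newly passed were all up, so mainly the set of called lists changed. With the main settings fry, which does not compare a list with the other genes, called 5 lists. Phosphate response (fry adjusted p = 8.6e-05), glycolysis (0.0478) and the INO80 complex, which includes the deleted ARP5, were down. Meiosis and sporulation and alpha-type mating genes were up.

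In all 99 of 6510 genes were called over the cycle, 66 higher and 33 lower in arp5∆. These are differences of mean log2 values, which at equal mean FPKM are lower for a gene with a wider swing. NOP2, for example, had a mean of 78.3 FPKM in wild type and 77.7 in arp5∆ but a log2 difference of 0.46. The smaller ranges in arp5∆ can thus raise differences of genes and list medians without more RNA on average, which bears on the split into higher and lower. The count depended on the phases: leaving out RB start left 1 gene, OX late 6, RB late 12, RC mid 26 and OX mid 59. Quantile normalization gave 65 genes, 35 higher and 30 lower. Other settings raised the count: the arp5∆ series moved by 2, 3 or 4 positions gave 289, 267 and 153 genes, leaving out the phase block 196, and taking the 24 libraries as separate samples 332. The moved series and the missing block were chosen after the data were seen. Rearranging the 12 means without regard to genotype gave counts as high in 5 of 100 splits, the real one included.

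Rapamycin was compared with the control culture at 45 min first. The nitrogen catabolite repression list, genes for the use of poor nitrogen sources, responded most: 20 of 22 members rose, with a median log2 change of 4.40. GAP1, the general amino acid permease gene, went from 18.0 ± 0.29 FPKM in the control to 3173 ± 141 (SD, n = 2; log2 change 7.38 ± 0.05 SE, adjusted p = 1.68e-09). MEP2, an ammonium permease gene, went from 24.4 ± 2.04 to 3260 ± 159 FPKM (7.004 ± 0.07), and DAL80 rose by 6.41. All 108 ribosome biogenesis genes fell (median -3.15), as did all 19 genes of RNA polymerases I and III and 132 of 136 cytosolic ribosomal protein genes (-2.42). DBP2 went from 693 ± 66.3 FPKM to 6.27 ± 0.82 (-6.58 ± 0.12, adjusted p = 3.71e-08), and RKI1, a pentose phosphate pathway gene, fell by 5.85. Genes of trehalose and glycogen metabolism rose in 13 of 15 cases (median 2.08, GPH1 by 3.75), stress genes in 17 of 26 (1.62, GAD1 by 3.83), with YDJ1 down by 1.97, and TCA cycle genes in 10 of 14 (1.51, CIT1 by 2.80). Autophagy genes rose in 14 of 35 cases (0.79, ATG8 by 2.80), and 10 of 37 oxidative phosphorylation genes rose (0.67). Phosphate response genes fell in 7 of 11 cases, PHO89 by 4.20. None of 53 G1/S, 16 G2/M and 8 histone genes passed at this time, and the histone median of -0.26 was 1.07 under quantile normalization.

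At 90 min cytosolic ribosomal protein genes had fallen furthest, 134 of 136 with a median of -3.92. RPL9A went from 4315 ± 40.1 FPKM in the control to 41.0 ± 5.39 (log2 change -6.69 ± 0.08, adjusted p = 2.06e-09), and RPS26B fell by 5.97. Ribosome biogenesis genes were down in 107 of 108 cases (-3.27). Amino acid biosynthesis genes, of which 8 rose and 7 fell at 45 min, now rose in 26 of 44 cases (median 1.32), ARG4 by 4.69 and ARG1 by 4.67, while 3 fell. LEU1 fell by 2.29. SNZ1, a vitamin B6 synthesis gene, rose by 6.20 ± 0.07, against 1.04 at 45 min. Core histone genes fell in 6 of 8 cases (median -1.51, and -0.16 under quantile normalization), HHF1 from 3176 ± 91.1 to 858 ± 52.2 FPKM, and 11 of 53 G1/S and DNA replication genes fell, led by CLB6 (by 1.98) and RNR1 (by 1.95). Stress genes rose in 21 of 26 cases (2.01), a-type mating genes in 5 of 7 (1.502, ASG7 by 2.504), autophagy genes in 22 of 35 (1.25) and peroxisomal genes in 12 of 36 (0.78), with CRC1, a carnitine carrier gene, up by 5.13. Nitrogen genes were still up in 21 of 22 cases (3.12). Of 15 glycolysis genes 1 rose, TDH1 by 2.03, and 1 fell, ADH1 (log2 change -1.51), and the others did not pass (median -0.35).

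**Figure D4:**
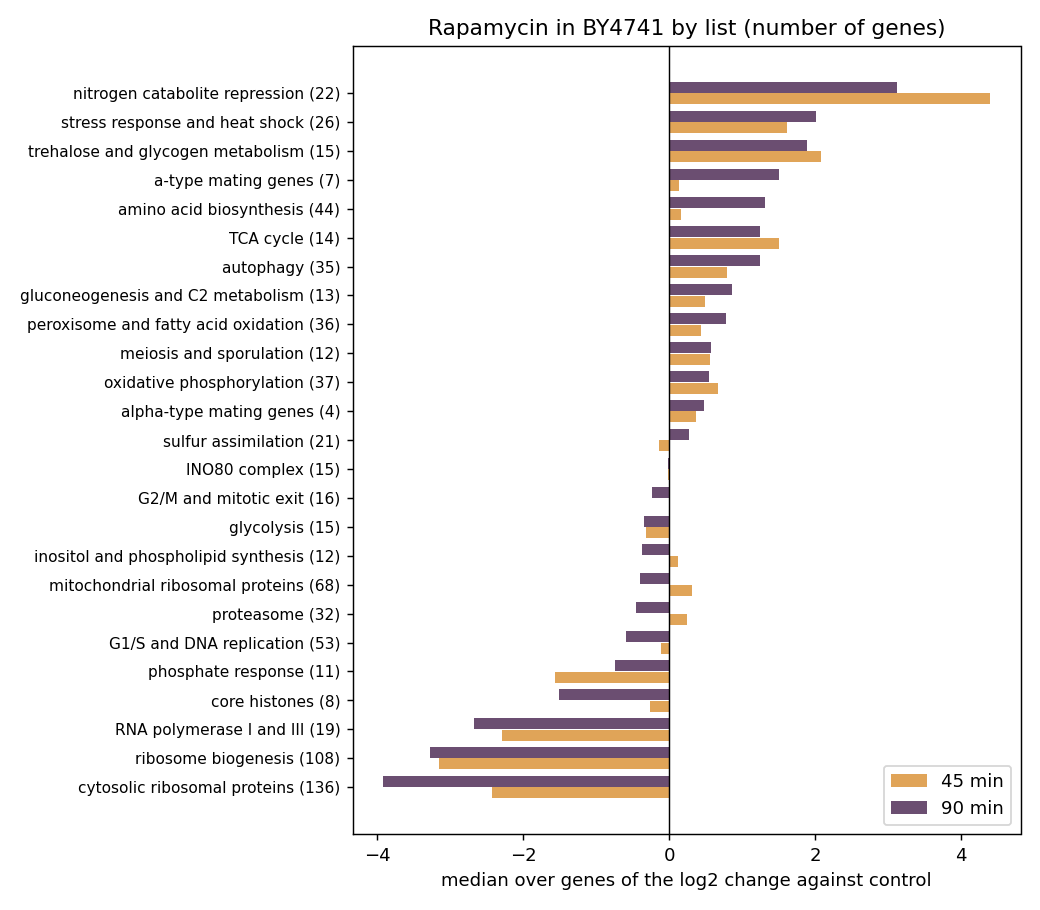
Median over each list's genes of the log2 change against the control after 45 min (orange) and 90 min (purple) of 30 nM rapamycin in BY4741, with the number of genes in brackets. Nitrogen catabolite repression genes stand highest (4.40 and 3.12) and cytosolic ribosomal protein genes lowest at 90 min (-3.92).

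At 45 min 1574 of 6333 tested genes were called, 709 higher and 865 lower, and at 90 min 2216, 1151 higher and 1065 lower (limma). List counts adjusted over the list alone were the same. Camera called 13 of 25 lists at 45 min and 18 at 90 min, none with an estimated correlation (lowest adjusted p = 0.285 and 0.270 with an estimated correlation; 4 lists each with an unadjusted p under 0.05). Fry, which does not compare a list with the other genes, called 22 lists at 45 min and 24 at 90 min. The times share their control libraries. Higher at both were 603 genes (independent lists would share 129) and lower at both 736 (146), with 4 genes called in opposite directions. The changes at 45 and 90 min had r = 0.89 across genes, where unchanged groups against the same controls gave 0.50 in simulation, and a covariance of 1.46 against a simulated 0.0136. With no effect at either time and the same shared controls, simulation called 0.1 genes in the same direction at both times, against 1339 observed. The controls are too few to split. Set directly against 45 min, 399 genes were higher and 297 lower at 90 min. Among these were 34 of 44 amino acid genes higher, 116 of 136 ribosomal protein genes lower, 5 of 8 histone genes lower and 9 of 22 nitrogen genes lower.

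The rapamycin responses were then looked up in arp5∆, since both bear on the control of growth. The 687 tested genes raised at 45 min had a median difference of 0.12 between arp5∆ and wild type over the cycle, and the 845 lowered ones one of -0.10. For the genes raised and lowered at 90 min the medians were 0.14 and -0.10. Camera called none of the 4 sets (adjusted p from 0.102 to 0.364, 1 set with an unadjusted p under 0.05; with an estimated correlation 0.866 for each). Of the 54 genes higher in arp5∆ among the 6075 tested in both sets of libraries, 10 were raised at 45 min (6.11 expected from independent lists) and 18 at 90 min (9.90 expected), while 4 were lowered at 45 min (7.51 expected) and 2 at 90 min (9.23 expected). Of the 33 lower ones, 2 were lowered at 45 min (4.59 expected) and 3 at 90 min (5.64 expected), while 5 and 6 were raised (3.73 and 6.05 expected). Across these genes the arp5∆ difference had r = 0.13 with the change at 45 min and 0.16 with that at 90 min. The strains and culture conditions differ between the sets. Of the genes in the 4 rapamycin sets, 76% to 93% cycled in wild type, and their spread between phases enters the test. In simulation the comparison over the cycle called 16% of single genes changed 2-fold, which lies at the minimum for a call, and 56% of those changed 3-fold. This bears on the overlaps of called genes and not on camera, whose power for these sets was not simulated. The lack of calls therefore does not show that arp5∆ lacks a response like that to rapamycin.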

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

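The comparison of ranges, the test on swapped libraries and that on damping were chosen after the results they concern were seen; the other tests were written before they were run, with the patterns themselves already known.

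The genotype difference differed between phases, by its own interaction test with the phases paired by label, in 4817 genes. The 12 named genes with the widest differences were ADY2 (15.04, log2), ADH2 (14.6), ACS1 (13.6), FDH1 (13.0), FOX2 (12.9), SPG1 (12.5), CTA1 (12.5), DBP2 (12.01), RGI2 (11.9), POX1 (11.8), NSR1 (11.6) and CAT2 (11.4). Tested directly, 399 genes were higher and 297 lower at 90 than at 45 min of rapamycin.

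A first pattern behind these differences is that arp5∆ phases resemble wild-type phases of other labels: 12 of 12 arp5∆ libraries did so, whereas a swap between the libraries of a pair of phases would leave most in place. If all arp5∆ phase names had been moved by a constant number of steps, most genes should match best at a single shift, and 68.7% of the 2029 genes cycling in both genotypes did so, at 2 steps (27.4% at 3 steps). The deposited table lists wild-type columns from RC start on but arp5∆ columns from RB start on, so that each arp5∆ phase stands 2 places later than its label; the labels were kept, since a place in a table is not a label. Against a constant shift, 6 of 12 libraries, those labelled OX mid, OX late and RB late, matched best at 3 steps. The matches also overlap, with none at RC mid or RB start. Between phase means centred within genotypes, OX late matched almost as well at 2 steps (r = 0.84 against 0.86). OX mid and RB late did not (-0.05 and 0.15, against 0.73 and 0.52 at 3 steps). RC mid, best at 2 steps, was nearly tied with 3 steps (0.72 against 0.71). RC start and RB start, also best at 2 steps (0.86 and 0.74), still had r = 0.57 and 0.60 at 3 steps. Over the 6 phases r ran from 0.52 (RB late) to 0.86 (OX late) at 3 steps. At 2 steps it ran from -0.05 (OX mid) to 0.86 (RC start). Gene by gene 2 steps matched better, with a median r of 0.81 against 0.64 at 3 steps. By list, 16 of 25 matched best at 2 steps and 4 at 3. G2/M and glycolysis matched best at the same label (r = 0.90 and 0.83, against -0.09 and -0.46 at 2 steps), with little range in arp5∆. So names moved by a constant number of steps may account for part of this pattern. They would account for all of it only if the sampled points of the cultures also differed, since some phases matched best at 2 steps and others at 3. A culture whose transcripts run ahead of the oxygen trace by which phases are named may account for part or all of the pattern too. That difference between the genotypes was not tested and cannot be tested without that trace.

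A second pattern is the smaller range in arp5∆. Scaling between libraries does not account for it, since under quantile normalization the median range of wild type still exceeded that of arp5∆ by 0.48. Time points that missed the extremes in arp5∆ would have to remove more than the loss of phases did in wild type, where the lowest median range over 4 of 6 phases was 0.77, narrowly above the 0.74 of arp5∆, so more uneven sampling stays open. Cells out of phase that damp all genes alike would give each list the ratio of random groups of the same size, whose genes resemble one another in wild-type profile and share its span of ranges, yet 3 of 24 lists lay outside (9 against single random genes, which ignore that members move together): G2/M below (median ratio 0.301 against 0.523), and G1/S (0.800 against 0.528) and cytosolic ribosomal proteins (0.636 against 0.496) above. Damping that differs with the shape of a profile stays open, and an effect of losing Arp5 on the amplitude of the cycle, or on how well the cells stay together, is a hypothesis on 1 culture per genotype.

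Another pattern is that of the 99 genes called over the cycle. Of 100 splits of the 12 means 5 gave as many genes, the real one included, and the highest other gave 1118. Of the 32 splits that exchange genotypes within phases 2 did, the real one and one with 726, and the remaining ones gave 0, so by these shares chance cannot be excluded for the count. Splits with several times the real count point to a structure of the samples: the one with 726 exchanges OX mid, OX late and RB start and so sets arp5∆ libraries that resemble wild-type RB late and RC start beside wild-type RC start, RC mid and RB late, which says little about chance. ARP5 was called over the cycle in every setting tried.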

How the results depend on the processing

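Chosen after the data were seen were the comparison without the phase block, the moved arp5∆ series, all settings of the range comparison, and those of gene lists, rapamycin sets and phase alignment other than the list tests and the use of all genes.

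For the counts, 455 recomputed values were the same by the 1.5-fold rule (or, for medians, within the SD between A and B) and 42 moved. For the named genes and lists 10711 kept their side of the threshold, 103 passed newly, 144 no longer passed and 4 changed sign. No cause of these moves was tested. Over the cycle (99 genes), quantile normalization gave 65, with 53.8% higher instead of 66.7%. Taking the 24 libraries as separate samples gave 332, and with a replicate block 323. Without the phase block there were 196, and with the arp5∆ series moved by 2, 3 and 4 positions 289, 267 and 153. Camera with an estimated correlation called 0 lists over the cycle, at 45 min and at 90 min. Fry called 5 over the cycle and 22 at 45 min. Under quantile normalization camera called 10 lists over the cycle, 8 up and 2 down, where it had called 4 up and 6 down. Genes with a range larger by at least 1 in arp5∆ (24) became 44 with a pseudocount of 0.1 and 42 without the filter. The median range in wild type (1.34) became 1.43 with that pseudocount, 1.30 without the filter and 1.26 under quantile normalization, and that in arp5∆ (0.742) 0.783 with the pseudocount and 0.782 under quantile normalization. Medians that changed sign, all under quantile normalization, were those of the proteasome (0.15) and cytosolic ribosomal proteins (0.00926) over the cycle, and of core histones (1.07) and glycolysis (0.72) at 45 min.

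Leaving out a library gave 2307 to 2356 genes at RC start, 1328 to 1386 at RC mid, 2821 to 2856 at OX mid, 1796 to 1842 at OX late, 1213 to 1276 at RB start and 1404 to 1464 at RB late. Leaving out a library or phase gave 1 to 106 over the cycle. Cycling genes were 4007 to 4104 in wild type and 2076 to 2138 in arp5∆, with 4790 to 4860 in the interaction. Ranges larger by at least 1 numbered 1897 to 1971 in wild type and 19 to 32 in arp5∆, and the median ranges were 1.34 to 1.36 and 0.742 to 0.762. Rapamycin gave 1514 to 1599 genes and 13 lists at 45 min, and 2193 to 2223 genes and 18 to 19 lists at 90 min. The replicate block moved no other count by over 1.5 times. The letters A and B showed no strong pairing: over 66 pairs of groups the A minus B differences correlated from -0.118 to 0.190 (mean 0.0322). A weak pairing by letter cannot be excluded this way. No block was run for rapamycin, whose replicates share no number. The mitochondrially encoded list has values only without the filter and so nothing to compare with. The alternatives for ATAC and for RNA with ATAC were not run.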

Other observations

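The tests on peak phases were written before they were run; the genes beside ARP5 and the RNAs of the last paragraph were chosen after their values were seen.

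Genes that rapamycin lowered in BY4741 were enriched for genes that wild-type cells of the cycle express most at OX mid. Of the 845 genes lowered at 45 min and tested in both sets 785 cycled in wild type, and of these 734 (93.5%) peaked at OX mid, against 41.1% of the 3774 cycling genes measured in both sets. Of the 571 cycling genes raised at 45 min, 253 (44.3%) peaked at RC start, against 25.2%, and 53 peaked at OX mid. Across 6075 genes the change at 45 min had r = -0.68 with the wild-type OX mid profile, 0.65 with RB late and 0.57 with RC start. In arp5∆ the lowest r was -0.65, for the libraries labelled RC start, and the highest 0.55, for those labelled OX late. High TORC1 output at OX mid may account for both shares (93.5% and 44.3%), as a hypothesis that was not tested with rapamycin in cycling cells. The nitrogen catabolite repression list goes against it. Rapamycin raised 20 of its 22 genes at 45 min, yet 18 of the 22 peaked at OX mid in wild type. Genes in these sets are not independent, and the lowered set includes 108 ribosome biogenesis and 132 cytosolic ribosomal protein genes.

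The genes next to ARP5 had no call over the cycle. NOP2 had 78.3 ± 103 FPKM in wild type and 77.7 ± 73.9 in arp5∆ (SD over 6 phases, log2 difference 0.46 ± 0.88 SE), and YNL058C 25.2 ± 14.4 and 30.8 ± 4.24 (0.45 ± 0.25).

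In wild-type RC start library A several RNAs without a poly(A) tail were higher than in library B from the same culture. SCR1, the RNA of the signal recognition particle, had 577 FPKM in A and 10.9 in B, LSR1, a spliceosomal RNA, 66.0 and 10.2, and the mitochondrial 21S_rRNA 28.3 and 2.01.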
